A study of Mus musculus with 32 samples.

How the data were processed

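The series holds 32 libraries of FVB/N mice, grouped from the submitters' labels: WT_B1a, Het_CLL, Mut_CLL, WT_CD8 and Mut_PTCL. DNA and RNA came from splenic cells sorted by FACS, per the labels, and the markers of the sort gate are not given in the sources used here. WGBS had 1 library per group (5), RRBS 2 libraries each of WT_B1a, Mut_CLL, WT_CD8 and Mut_PTCL (8), and RNA-seq 19 libraries (WT_B1a 2, Het_CLL 4, Mut_CLL 8, WT_CD8 2, Mut_PTCL 3). Tumours of CLL were compared with WT_B1a and PTCL with WT_CD8. The comparisons, tests, gene lists and most alternatives were fixed before the data were examined; what was chosen later is named as such.

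The deposited WGBS files hold methylated and unmethylated read counts per CpG cytosine on mm10, and the deposited RRBS files hold counts of methylated calls and of all calls per cytosine on mm9. The submitters' processing notes list TopHat2, Cufflinks, Bismark 0.14.3 and Bowtie2 2.2.3 and the builds mm10 and mm9, without the role of each per assay, and filters on reads are not given in the sources used here. The RRBS files list no site under 5 calls, whereas the WGBS files list sites with 1 call. The RNA values are FPKM that the authors computed per group with Cuffdiff, per the file headers and labels. The same deposited tables give the authors' test statistic, a score, and a p-value and q-value per gene, and these were used as they stand, because no value per library is in the files. The authors normalized each table alone: the WT_B1a group is listed with other FPKM values in the Het_CLL table, which holds assembled loci, than in the Mut_CLL table, so values were compared within a table.

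Methylation was computed as methylated calls over all calls, in percent, with both strands of a CpG joined. WGBS sites needed at least 5 calls in both libraries of a comparison, and a region at least 5 such CpGs. Regions were 1 kb tiles, annotated gene loci and gene-end windows, and a region counted as lower or higher at a difference of at least 30 percentage points. The planned promoters could not be placed, because the mm10 annotation carries no strand. Gene loci took their place, as the design allowed, and windows of 1000 bp on each side of the CpG-richer gene end were added after seeing the data. That end was under 20% methylated in 24.4% of genes in WT_B1a and the other end in 1.61% of genes. No mm9 annotation was used here, so RRBS was analysed as tiles and mean levels.

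WGBS depth was 693153167, 643055218, 1027689683, 850107844 and 898171153 calls in WT_B1a, Het_CLL, Mut_CLL, WT_CD8 and Mut_PTCL, with median coverage per CpG of 21, 16, 10, 14 and 16, and 89.0%, 85.0%, 77.2%, 85.1% and 88.0% of sites at 5 calls or more. Methylation of chromosome M, a bound on incomplete conversion, was 3.41%, 3.31%, 4.28%, 3.78% and 4.09%. RRBS libraries held 58971470 to 145748978 calls, 816970 sites with at least 10 calls in all 8 libraries, and 69973 tiles. Binomial counting error was given as 95% Wilson intervals, which cover counting error alone and not the variation between animals. Their widest span was 26.2 points in the named Het_CLL regions (median 8.63), 27.1 in Mut_CLL (median 9.28) and 19.0 in Mut_PTCL (median 8.50), and 0.00647 points for the mean levels.

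RRBS tiles needed at least 3 CpGs with at least 10 calls in every library. Methylated and unmethylated counts per tile were tested with the edgeR 4.0.16 quasi-likelihood test in 1 fit of all 8 libraries. The fit had an effect for each library and the group as a term on the methylated counts. All groups shared 1 estimate of the spread, although tumour libraries varied more than normal ones. In tiles between 30% and 70% methylation, overdispersion between libraries was 0.0591 in Mut_CLL and 0.0569 in Mut_PTCL. It was 0.000262 in WT_B1a and 0.00310 in WT_CD8. The adjusted p-values and tile counts rest on the shared estimate. A tile was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 points. Tile counts at an unadjusted p under 0.05 also ask for that difference, unless said otherwise. Where leaving out a library leaves an arm with 1 sample, the lone sample is assumed to vary like the other groups. Alternatives used limma 3.58.1 on tile levels. RRBS mean levels were tested by exact permutation, where the smallest two-sided p of a 2 against 2 comparison is 0.333. The difference of the tumour effects was tested as an interaction, Mut_CLL minus WT_B1a against Mut_PTCL minus WT_CD8.

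Expression calls used the authors' q under 0.05, at least 1 FPKM in either group and an absolute log2 fold of at least 1, and gene lists counted members at q under 0.05. A total of 18 gene lists was fixed: DNA methylation machinery, cell cycle, B-cell identity, B-1a cell markers, CLL-associated genes, B-cell receptor and NF-kB targets, T-cell identity, cytotoxic effector genes, inhibitory receptors and exhaustion genes, myeloid markers, erythroid markers, plasma-cell markers, lymphoma oncogenes, p53 targets, interferon-stimulated genes, germline genes, imprinted genes and developmental regulators. The lists share no gene. List medians were placed among 10000 random lists of the same size, matched on the normal library's methylation in WGBS and on mean expression in RNA, and ranges give the middle 95% of the random lists. Overlaps of the CLL comparisons were set beside the overlap of independent lists and a simulation with a shared control.

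Named genes follow a fixed rule per comparison: Dnmt3a; the 5 largest rises and 5 largest falls in expression that passed, with at least 5 FPKM in the higher group and above 0 in the lower; the 5 largest losses and gains over regions with at least 10 CpGs; the 5 largest folds among genes that lost at least 30 points and were higher, or gained and were lower; the 5 largest RRBS falls and rises with both tumour libraries beyond both normal libraries; and up to 4 members per list that passed, by size. The text names a part of these genes, and some genes that the rule selects are not reported here.

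The procedures were tested on simulated data. Planted WGBS drops of 40 points were recovered in 97% to 100% of regions, and 0 unchanged regions were called. RRBS falls of 25 points planted in 100 tiles were recovered in 98% at an overdispersion of 0.001 between libraries and in 0% at 0.01 or at the spread measured here, where 97% and 88% had an unadjusted p under 0.05; 0 unchanged tiles were called. The RRBS test can therefore miss real differences when few tiles change. At the spread measured here, 9.48% of unchanged tiles under 5% methylation had an unadjusted edgeR p under 0.05 at any difference. At middle levels it was 3.94%. For expression lists, 3% of unchanged lists fell outside the random range.

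Alternatives fixed beforehand covered coverage limits, the size of the difference, centring of tiles and loci on the median difference, RRBS filters, limma, a replicate block, leaving out single libraries, and stricter q and FPKM limits. Alternatives chosen after seeing the data left out sites with more than 200 calls, varied the gene-end windows (centring, 500 bp on each side, either gene end and the other settings), used limma with single libraries left out, and left out regions and genes where WT_CD8 could have moved WT_B1a. Sequence-based analyses were not analysed here, since no genome was at hand. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.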

Results

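Mouse lymphoid tumours that arose after deletion of Dnmt3a, the gene of a de novo DNA methyltransferase, were compared with normal lymphocytes of the spleen. The series holds 32 libraries in 5 groups. WT_B1a is normal B-1a cells, an innate-like B-cell subset, and WT_CD8 is normal CD8+ T cells. Het_CLL and Mut_CLL are chronic lymphocytic leukaemias, tumours of B cells, with 1 and with both Dnmt3a alleles deleted, and Mut_PTCL is peripheral T-cell lymphoma with both alleles deleted. Whole-genome bisulfite sequencing (WGBS, build mm10) covers each group with 1 library. Reduced-representation bisulfite sequencing (RRBS, build mm9) covers 4 groups, Het_CLL left out, with 2 libraries each. RNA-seq covers 19 libraries, read here as the 3 tables the authors deposited, with 1 pooled FPKM value per group. The labels do not say which libraries come from separate animals, so the p-values measure only the spread between these samples. WGBS has no replicates, so no WGBS difference was tested, and regions are counted where a pair of libraries differed by at least 30 percentage points.

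The deleted part of Dnmt3a was visible in the WGBS coverage. Over the mm10 window from 3900000 to 3901999 on chromosome 12, coverage relative to the flanks was 0.520 of the normal level in Het_CLL, 0.167 in Mut_CLL and 0.252 in Mut_PTCL. In the next window, from 3902000 to 3903999, the ratios were 0.366 in Het_CLL, 0 in Mut_CLL and 0.0495 in Mut_PTCL. Dnmt3a RNA passed no test: the authors' deposited table lists 10.4 FPKM in WT_B1a and 9.99 in Het_CLL (q = 0.923), 11.5 and 9.18 in the Mut_CLL table (q = 0.494), and 9.83 in WT_CD8 and 6.45 in Mut_PTCL (q = 0.117).

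**Figure D1:**
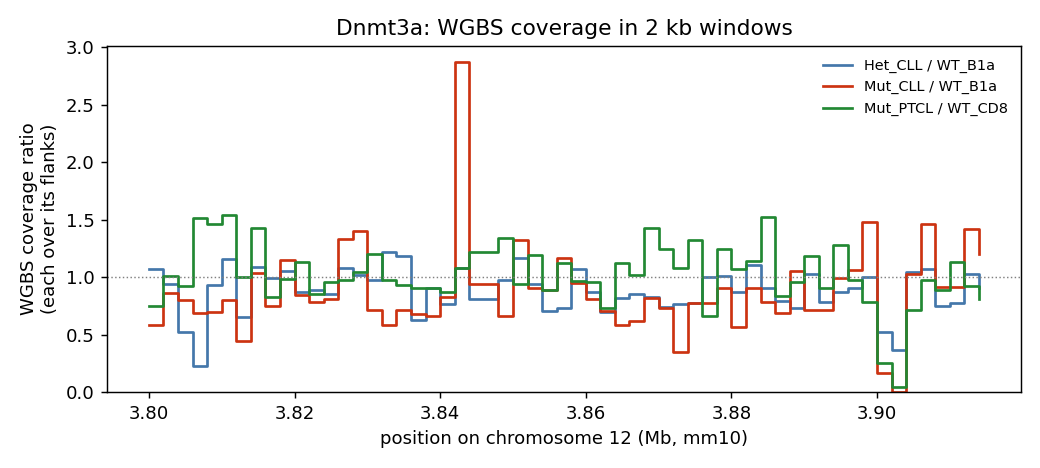
WGBS coverage over Dnmt3a in 2 kb windows, each library relative to its flanks and divided by the normal library of its lineage. Between 3902000 and 3903999 on chromosome 12 (mm10) the ratio was 0.366 in Het_CLL, 0 in Mut_CLL and 0.0495 in Mut_PTCL.

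**Figure D2:**
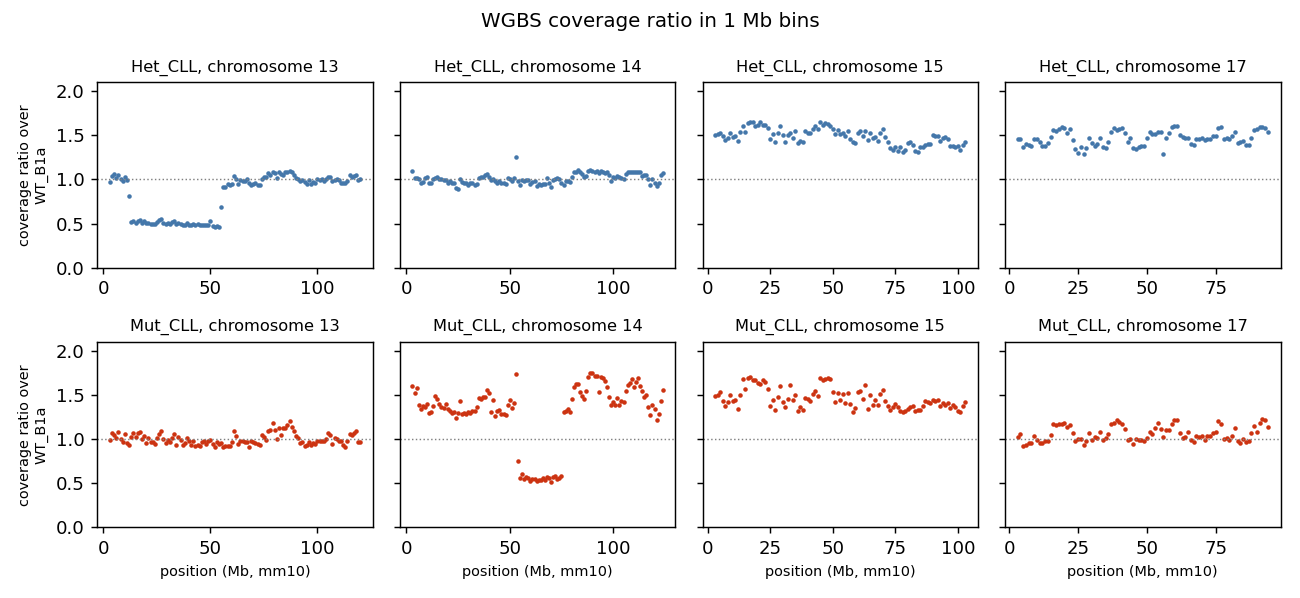
WGBS coverage of Het_CLL and Mut_CLL over WT_B1a in 1 Mb bins of chromosomes 13, 14, 15 and 17. Chromosome 15 stood at 1.49 in Het_CLL and 1.44 in Mut_CLL.

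Het_CLL carried less methylation than WT_B1a over genes that define B cells. The ends of Cd79b and Cd79a, the signalling chains of the B-cell receptor, held 0.806% and 0.211% methylation in Het_CLL, against 61.1% and 44.5% in WT_B1a. Ms4a1, the gene of the surface protein CD20, went from 59.2% (95% Wilson interval 52.9 to 65.2, 245 calls) to 0.806% (0.221 to 2.89, 248 calls), and Blnk, an adaptor of the same receptor, from 45.6% to 0.637%. The opposite difference was seen at T-cell genes: Lat and Lck, which relay T-cell receptor signals, were at 48.8% and 48.6% in WT_B1a and at 81.9% and 78.6% in Het_CLL, and Bcl11b, a regulator of T-cell commitment, at 3.87% (2.81 to 5.31) and 37.7% (33.9 to 41.6). These levels belong to windows of 1000 bp on each side of the CpG-richer end of each gene, a measure chosen after seeing the data. T cells among the sorted WT_B1a cells, taken up below, could give differences of both kinds. The named genes and the gene lists were not restricted by WT_CD8.

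By the fixed gene lists, 6 of the 16 measured B-cell identity genes were lower in Het_CLL by at least 30 points and 0 higher, with a median difference of -22.7 points (random lists matched on the normal level: -9.46 to 0.541). B-1a cell markers had 3 of 14 lower (median -12.6, random -7.52 to 0.732), among them Zbtb32 (75.6% to 27.5%), Cd5 (41.4% to 4.27%) and Il10 (43.9% to 10.9%). T-cell identity genes had 4 of 19 higher and 0 lower (median 11.5, random -9.65 to 1.05), with Runx3 at 20.9% and 58.8%. Plasma-cell markers (1 of 6 lower, Irf4 at 34.0% and 1.62%; median -14.6, random -12.0 to 4.17) and interferon-stimulated genes (0 of 17; median -12.5, random -9.11 to 0.184) also lay below their random range. Developmental regulators lay above it (1 of 36 higher, Hoxa13 at 10.5% and 60.0%; median 9.70, random -4.63 to -0.305). Among lymphoma oncogenes, Jdp2 (54.0% to 7.69%) and Evi5 (78.6% to 44.6%) were lower and Kit (15.3% to 54.2%) higher, with a median of -0.512. Single members were lower in DNA methylation machinery (Uhrf1, 65.8% to 26.2%; median of 14 genes -7.16), B-cell receptor and NF-kB targets (Nr4a1, 64.5% to 17.3%; -2.01), cytotoxic effector genes (Fasl, 83.9% to 48.7%; -1.39) and erythroid markers (Hba-a1, 68.4% to 37.4%; -4.97). No member differed by 30 points among cell cycle genes (median -2.33), CLL-associated genes (-1.60), inhibitory receptors and exhaustion genes (-2.98), myeloid markers (-7.29), p53 targets (-3.71), germline genes (-3.35) and imprinted genes (-5.25), and these medians lay inside their random ranges. Over whole gene loci, B-cell identity (median -21.0), B-1a cell (-10.2) and plasma-cell markers (-21.5) again lay below, and T-cell identity genes (7.69) and developmental regulators (2.60) above. There, interferon-stimulated genes lay inside the range (-4.02, random -5.52 to -2.41), and cytotoxic effector genes above it (-0.972, random -6.03 to -1.80).

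Over whole gene loci, the largest losses in Het_CLL were at Ccl17, a chemokine (70.9% to 0.637%), Tlr9, a sensor of CpG DNA (67.9% to 3.20%), the pseudogene H2-Ea-ps (76.1% to 12.2%), Ly6d (64.3% to 1.68%) and Ly6a (61.1% to 2.11%), and the largest gains at Rprm (6.05% to 52.6%) and Egr3 (9.40% to 54.3%). Of 19776 gene loci, 107 were lower in Het_CLL and 23 higher, and of 19763 gene-end windows 363 were lower and 149 higher. Of 1589084 tiles of 1 kb, 32289 were lower and 4324 higher, with a median difference of -3.31 points. The mean level over CpGs with at least 5 calls was 78.2% in Het_CLL and 80.6% in WT_B1a, a difference of -2.41 points (-4.29 with sites of more than 200 calls left out, chosen after seeing the data). Draws of unchanged levels at the same depths gave 7 lower and 11 higher tiles and 0 loci. T-cell genes stood out in WT_B1a, so calls were also restricted, after seeing the data, to regions where WT_CD8 could not have moved the WT_B1a level towards the call. That left 47 loci lower and 11 higher, 218 gene-end windows lower and 70 higher, and 13378 tiles lower and 1759 higher. The restriction kept 43.9% of the lower loci, 60.2% of the lower gene-end windows and 43.2% of the lower tiles, against 81.4%, 65.8% and 64.2% of all such regions. Of the higher windows and tiles it kept 47.0% and 43.6%, against 34.4% and 35.9% of all, and of the higher loci 11 of 22, against 18.6%.

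Mut_CLL lost methylation across the genome, and its B-lineage genes differed from WT_B1a by more than that loss. T cells among the sorted WT_B1a cells, taken up below, could give such a difference. The named genes and gene lists were not restricted by WT_CD8. Spn, the gene of the surface protein CD43 that marks B-1 cells, held 74.4% (70.9 to 77.7) in WT_B1a and 18.9% (15.1 to 23.5) in Mut_CLL. Uhrf1, which recruits the maintenance methyltransferase Dnmt1 to replicating DNA, held 63.8% and 6.59%. The checkpoint receptor gene Ctla4 went from 54.5% to 3.72%, Ms4a1 from 56.9% to 9.66% and Cd79b from 61.5% to 8.57%. Bcl11b was again higher, at 2.89% in WT_B1a and 44.3% in Mut_CLL.

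B-1a cell markers had 7 of 14 members lower in Mut_CLL (median -29.0 points, random lists -18.0 to -2.64), with Itgam (67.8% to 27.0%), Zbtb32 (76.0% to 23.0%) and Cd5 (57.3% to 17.1%). B-cell identity genes had 6 of 15 lower (median -24.8, random -18.5 to -3.20), with Cd22 at 32.3% and 2.33%, and plasma-cell markers 2 of 6 (median -27.5, random -22.9 to -1.34), Tnfrsf17 and Irf4. T-cell identity genes (1 of 18 higher; median -2.72, random -15.6 to -3.29), developmental regulators (0 of 34 in either direction; 3.42, random -6.25 to -1.98) and germline genes (1 of 21 lower, Piwil2; -5.57, random -17.4 to -7.87) lay above their random ranges. Imprinted genes had 5 of 25 lower, Peg13 (73.0% to 31.7%), Airn (75.1% to 34.6%), Sgce, Peg10 and Meg3, with a median of -15.1 inside the range. Lymphoma oncogenes had 4 lower, with Pvt1 (46.4% to 2.99%) and Vav1 (42.6% to 2.75%), and 2 higher, Kit (22.7% to 64.8%) and Mycn (1.22% to 33.2%), with a median of -2.34. B-cell receptor and NF-kB targets had 5 of 17 lower, with Nfkb1 at 72.8% and 31.7% (median -5.91), cytotoxic effector genes 3 of 14 (-13.9), DNA methylation machinery 2 of 14 with Dnmt3b at 59.8% and 26.1% (-13.9), and p53 targets 2 of 16 (-12.9). Myeloid markers (Cd68, 92.9% to 42.5%; median -7.19), erythroid markers (Hba-a1; -15.5) and interferon-stimulated genes (Usp18; -15.8) had 1 member lower each. Cell cycle genes (median -7.71), CLL-associated genes (-5.16) and inhibitory receptors and exhaustion genes (-9.25) had 0 lower and 0 higher, and the medians of these lists lay inside their random ranges. Over whole gene loci, germline genes lay inside the range (-14.4, random -16.5 to -10.7). There, B-cell receptor and NF-kB targets (-20.3, random -18.9 to -9.55) and inhibitory receptors and exhaustion genes (-18.8, random -18.7 to -9.07) lay below it. The other lists kept their place over loci.

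Among gene loci in Mut_CLL, Cdk2ap2 (71.4% to 3.66%), the stress-response regulator Atf4 (76.7% to 10.7%) and Crip1 (72.2% to 11.9%) were among the largest losses, and the homeobox genes Irx5 (7.75% to 46.0%) and Irx1 (11.5% to 46.1%) among the largest gains. Gli3, a transcription factor of Hedgehog signalling, had the largest gain at a gene end, from 3.25% to 68.9%. Of 19580 gene loci 983 were lower and 15 higher, and 97.3% of loci lay below WT_B1a. Of 19337 gene-end windows 1526 were lower and 137 higher, and of 1450882 tiles 204275 were lower and 1846 higher, with a median of -13.4 points. Tiles of 5 to 9 CpGs were lower by a mean difference of -16.7 points, those of 10 to 19 CpGs by -12.8 and those of 20 to 39 CpGs by -7.24, whereas 21 of the 165 tiles with at least 40 CpGs and under 20% methylation in WT_B1a were higher. Counting error gave 26 lower and 29 higher tiles. With differences centred on their median, 56182 tiles were lower and 8496 higher, 164 loci lower and 61 higher, and 577 gene-end windows lower and 328 higher. Where WT_CD8 could not have moved WT_B1a towards the call, 628 loci, 1110 gene-end windows and 124887 tiles remained lower, which is 64.3%, 72.9% and 62.9% of those called, against 82.8%, 68.2% and 64.6% of all such regions. Of the higher regions 10 of 15 loci (66.7%), 59 gene-end windows (43.1%) and 955 tiles (54.9%) remained, against 17.3%, 32.0% and 35.6% of all.

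The genome-wide mean of Mut_CLL depended on a few positions of very high coverage. Pooled over calls, Mut_CLL stood at 78.0% and WT_B1a at 80.6%, a difference of -2.64 points, and the mean over sites differed by -13.8 points (65.4% and 79.3%). Positions with more than 2000 calls held 71.9% of all Mut_CLL calls and 31.5% of WT_B1a calls, and without sites of more than 200 calls the pooled difference was -15.3 points. The widest 95% Wilson interval of these means spans 0.00647 points.

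Mut_CLL had less methylation than Het_CLL, a comparison that does not use the WT_B1a library. The median difference was -9.52 points over 1 kb tiles, with 81.0% of the tiles lower in Mut_CLL, and 123364 tiles were lower and 3080 higher by at least 30 points. Gene ends differed by a median of -5.09 points, with 787 lower and 52 higher.

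The same gene ends often lay lower in both CLL libraries, among them Cd79b, Ms4a1, Cd5, Zbtb32, Il10, Irf4 and Uhrf1. Of the gene-end windows measured in both, 232 were lower in both libraries, where independent lists would share 27.4. For gene loci the overlap was 73 (independent 5.06), and 66 gene-end windows, Bcl11b and Kit among them, were higher in both (independent 0.988). Simulated unchanged libraries against the shared WT_B1a library shared 0 in each case, but they carry counting error alone, which calls at most 1 such region, so that 0 says nothing about differences between animals. Part of the excess may come from the shared WT_B1a library: 131 gene-end windows and 27 loci lower in both were left where WT_CD8 could not have moved WT_B1a towards the call.

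Mut_PTCL had less methylation than WT_CD8 at genes of killer lymphocytes. Klrd1, a subunit of natural killer cell receptors, went from 84.0% (77.8 to 88.8) to 9.83% (6.64 to 14.3). Prf1, the pore-forming perforin, went from 62.7% to 12.2%, Gzmb, the protease granzyme B, from 56.4% to 13.7%, and Il2rb, the interleukin 2 receptor beta chain, from 44.2% to 4.52%. The antiviral genes Oas3 and Usp18 went from 78.3% to 10.3% and from 51.5% to 8.67%. Cytotoxic effector genes had 7 of 15 lower (median -25.1 points, random lists -8.89 to 1.23). Interferon-stimulated genes had 2 of 17 lower (-12.0, random -9.79 to 1.18), and T-cell identity genes 0 of 19 (-7.74, random -5.38 to 2.06). Below their ranges also lay p53 targets (1 of 16, Zmat3; -7.66, random -7.48 to 1.77) and lymphoma oncogenes (2 of 18, Jdp2 and Evi5; -2.38, random -2.01 to 0.842). Imprinted genes (0 of 25 by 30 points; median 5.64, random -9.37 to 0.483), erythroid markers (0 of 7; 7.21, above 99.8% of random lists) and developmental regulators (1 of 36 lower, Hoxa5, 88.8% to 47.3%; 1.37, random -3.51 to 0.975) lay above. The other lists lay inside their random ranges: DNA methylation machinery (median -7.59), cell cycle (-0.201), B-cell identity (-0.595; Cd22 lower, 54.5% to 11.1%), B-1a cell markers (-0.808; Spn lower), CLL-associated genes (-2.75), B-cell receptor and NF-kB targets (-4.57; Traf1 and Ccl4 lower), inhibitory receptors and exhaustion genes (-4.05), myeloid markers (-1.92), plasma-cell markers (-7.78) and germline genes (-2.11). Over whole gene loci, imprinted genes (-4.50, random -6.05 to -1.93), erythroid markers (-2.52, random -9.62 to -0.204) and developmental regulators (-1.36, random -6.44 to -0.328) lay inside. There, B-1a cell markers (-8.63, random -7.65 to -1.05), B-cell receptor and NF-kB targets (-8.04, random -7.73 to -1.20) and plasma-cell markers (-10.7, random -10.4 to 0.109) lay below. The other lists kept their place, cytotoxic effector genes with 9 of 16 lower, 1 higher and a median of -33.8.

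The largest losses over gene loci in Mut_PTCL included the epithelial junction gene Cldn4 (84.7% to 18.4%) and the natural killer receptor genes Klrc1 (88.9% to 25.2%) and Klre1 (71.3% to 8.04%). The largest gains were at Pou3f4 (15.6% to 57.4%) and Rprm (9.44% to 49.4%), and Tle1, a transcriptional corepressor, gained at its end (0.207% to 52.8%). Of 19809 gene loci 165 were lower and 12 higher, of 19876 gene-end windows 283 lower and 90 higher, and of 1573602 tiles 43005 lower and 3555 higher (median -3.19), where counting error gave 14 and 6 tiles. The pooled means were 79.7% in Mut_PTCL and 79.1% in WT_CD8, a difference of 0.530 points, which turned to -4.71 without sites of more than 200 calls and to -4.63 as a mean over sites. Mut_CLL and Mut_PTCL, which share no library, were lower together at 111 gene-end windows (independent 21.2) and higher together at 24 (independent 0.574). Independent lists assume that every window is equally likely to be called. No restriction by WT_CD8 was applied to these counts, and T cells among the WT_B1a cells, taken up below, would make the normal libraries alike. The overlap therefore does not show what the tumours share apart from their normal cells.

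RRBS carried both tumours with replicates, tested with 1 estimate of the spread for tumour and normal libraries, although the tumour libraries varied more. Most of the tiles that rose had little methylation in normal cells, and most of those that fell had an intermediate level. A tile near either end of the scale can change by 10 points in a single direction only, so its level limits the call. In Mut_CLL, the tile on chromosome 6 from 98964000 to 98964999 (mm9) fell to 8.12% ± 3.11 (SD, n = 2) from 94.2% ± 4.07 (n = 2) in WT_B1a (edgeR adjusted p = 0.00467). The tile on chromosome 5 from 113443000 to 113443999 rose to 80.5% ± 6.00 from 6.54% ± 0.0818 (n = 2 each, edgeR adjusted p = 0.00734). A tile of 46 CpGs on chromosome 15 from 87374000 to 87374999 rose to 69.7% ± 9.94 from 7.26% ± 1.76 (n = 2 each, edgeR adjusted p = 0.0360). No mm9 gene annotation was used here, so RRBS tiles are named by position. Of 69973 tiles, 2647 fell and 1030 rose in Mut_CLL by edgeR (median differences of -31.4 and 29.2 points), each with both tumour libraries beyond both normal libraries. Of 24584 tiles under 20% in WT_B1a, 939 rose (3.82%) and 219 fell, and of 31018 tiles between 20% and 80%, 1996 fell (6.43%). Chance places both tumour libraries beyond both normal libraries, on a given side, in 1 of 6 splits. Without WT_B1a replicate 1, edgeR and limma left 0 tiles in either direction (unadjusted p under 0.05 by edgeR: 4518 lower, 1672 higher; by limma: 4291 and 1734). Without WT_B1a replicate 2 both tools also left 0 (unadjusted p under 0.05: 4724 and 1705 by edgeR, 4474 and 1758 by limma). Without Mut_CLL replicate 2 the counts were 5634 and 2327 by edgeR, and without Mut_CLL replicate 1, 650 tiles were higher by limma.

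In Mut_PTCL, the tile on chromosome 13 from 38594000 to 38594999 fell to 4.80% ± 5.93 from 94.9% ± 0.144 in WT_CD8 (n = 2 each, edgeR adjusted p = 0.0195). A tile of 13 CpGs on chromosome 6 from 52153000 to 52153999 fell to 5.88% ± 1.12 from 88.2% ± 2.17 (n = 2 each, edgeR adjusted p = 0.00714). A tile of 19 CpGs on chromosome 4 from 104039000 to 104039999 rose to 65.2% ± 0.338 from 3.46% ± 0.214 (n = 2 each, edgeR adjusted p = 0.0143). In all, 759 tiles fell and 437 rose (median differences of -35.1 and 26.9 points). Of 24285 tiles under 20% in WT_CD8, 368 rose, and of 30332 tiles between 20% and 80%, 554 fell. Without WT_CD8 replicate 1, edgeR and limma left 0 tiles in either direction (unadjusted p under 0.05: 2470 lower and 1342 higher by edgeR, 2403 and 1376 by limma). Without WT_CD8 replicate 2 both tools also left 0 (unadjusted p under 0.05: 2530 and 1484 by edgeR, 2444 and 1490 by limma). Without Mut_PTCL replicate 2 the counts were 1462 and 870 by edgeR and 1319 and 892 by limma.

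**Figure D3:**
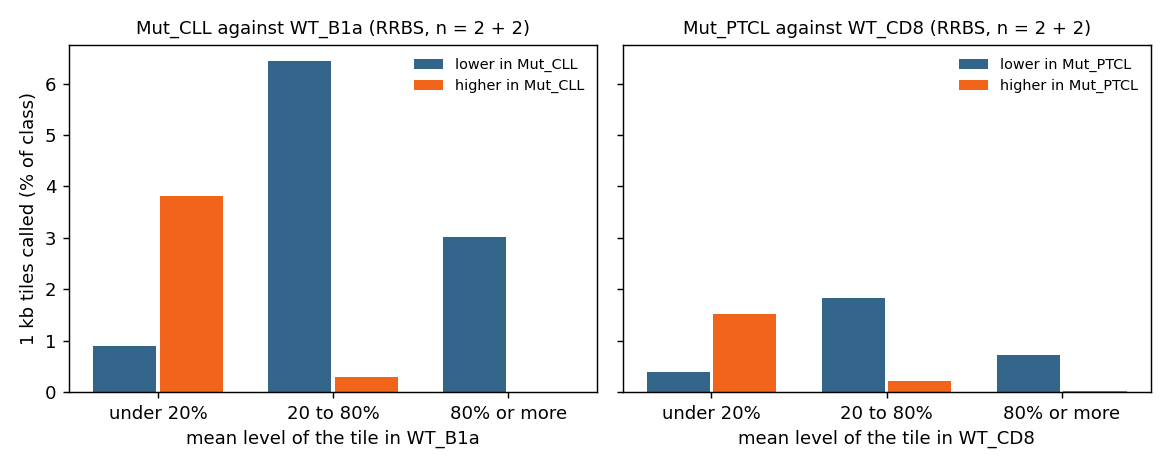
Share of RRBS tiles called lower and higher in each tumour, by the mean level of the tile in the normal cells. In Mut_CLL 3.82% of the tiles under 20% in WT_B1a rose and 6.43% of the tiles between 20% and 80% fell.

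The tile on chromosome 4 from 138368000 to 138368999 rose in both tumours, to 78.9% ± 9.07 from 9.50% ± 0.747 in Mut_CLL (n = 2 each, edgeR adjusted p = 0.0101), and to 76.4% ± 13.8 from 10.2% ± 0.625 in Mut_PTCL (n = 2 each, edgeR adjusted p = 0.0224). Tiles that rose in both numbered 312, where independent lists would share 6.43, and tiles that fell in both numbered 326 (independent 28.7). The WT_B1a and WT_CD8 libraries were nearly alike in RRBS and no restriction by WT_CD8 was applied to these counts, so the overlap does not show what the tumours share apart from their normal cells. The change differed between the tumours, as an interaction in edgeR, at 219 tiles. At 166 of them Mut_CLL fell relative to Mut_PTCL (median differences of -48.5 and 0.0516 points), and at 53 Mut_PTCL fell relative to Mut_CLL (-57.1 and -4.32). The count was 0 with the replicate number as a block, although these numbers do not pair the samples. It also changed with every library left out. By edgeR it was 0 without WT_B1a replicate 1 (unadjusted p under 0.05: 2717 tiles), WT_B1a replicate 2 (2857), WT_CD8 replicate 1 (3189), WT_CD8 replicate 2 (3142) or Mut_PTCL replicate 2 (5816). It was 540, 771 and 449 without Mut_CLL replicate 1, Mut_CLL replicate 2 and Mut_PTCL replicate 1. By limma it was 172 with all libraries and 0 without WT_B1a replicate 1 (unadjusted p under 0.05: 2683), WT_B1a replicate 2 (2813), WT_CD8 replicate 1 (3155), WT_CD8 replicate 2 (3099), Mut_PTCL replicate 1 (6545) or Mut_PTCL replicate 2 (5545). It was 343 and 497 by limma without Mut_CLL replicates 1 and 2.

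Between WT_B1a and WT_CD8 libraries of RRBS the mean absolute difference per site was 2.91 to 3.08 points (correlation 0.982 to 0.984). That was little more than between the WT_CD8 replicates (2.91, 0.986), and more than between the WT_B1a replicates (2.08, 0.994). Mut_CLL and WT_B1a libraries differed by 5.66 to 7.81 points. The Mut_CLL replicates differed from each other about as much (6.87, 0.916), and the Mut_PTCL replicates differed by 6.06 points (0.933). The normal cell types differed at 130 tiles by edgeR. That count became 0 without WT_B1a replicate 1 (unadjusted p under 0.05: 1029; limma 0 and 964), WT_B1a replicate 2 (1078; limma 0 and 1002), WT_CD8 replicate 1 (1222; limma 0 and 1146) or WT_CD8 replicate 2 (1199; limma 0 and 1115). The RRBS mean level showed no difference that the design could resolve. It was 23.8% ± 1.90 in Mut_CLL and 26.02% ± 0.811 in WT_B1a (SD, n = 2 each; exact permutation p = 0.333, two-sided, the smallest that 6 splits allow), and 26.2% ± 1.95 in Mut_PTCL and 25.5% ± 1.64 in WT_CD8 (n = 2 each; exact permutation p = 0.667, two-sided). Mut_CLL lay -2.20 points from WT_B1a, and -0.363 points as a mean over sites. The Mut_PTCL difference of 0.708 points turned negative without Mut_PTCL replicate 1 (-0.669) and without WT_CD8 replicate 2 (-0.454).

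RNA of Het_CLL showed less of the T-cell genes and more of a set of B-1a and plasma-cell genes than WT_B1a. Lat fell from 140.4 to 2.23 FPKM (log2 fold -5.98) and Cd3d, a chain of the T-cell receptor complex, from 67.5 to 1.59 FPKM (-5.41) in the authors' deposited table. Zbtb32, a transcriptional repressor, rose from 9.66 to 115 FPKM (3.58), and Igj, the joining chain of secreted antibodies, from 13.9 to 238 FPKM (4.10) in the authors' deposited table. S100a8, an abundant neutrophil protein, rose from 7.22 to 346 FPKM (5.58) in the authors' deposited table. Satb1, a chromatin organiser of T cells, fell from 157 to 2.03 FPKM (-6.28) and Cd6, a T-cell surface receptor, from 52.8 to 0.781 FPKM (-6.08) in the authors' deposited table.

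Of 19 measured T-cell identity genes 11 fell and 0 rose in Het_CLL (12 fell adjusted over the list alone; median log2 fold -5.13, random lists -0.33 to 0.39). CLL-associated genes had 1 of 9 higher and 5 lower (2 and 5 adjusted over the list alone; median -1.17), with Tcf7, Zap70 and Lef1, which T cells also express, at 203 to 4.34, 28.4 to 0.799 and 81.7 to 5.21 FPKM in the authors' deposited table. B-1a cell markers had 4 of 14 higher, with Itgam (1.47 to 13.6 FPKM) and Pdcd1lg2 (3.92 to 21.7 FPKM), and 2 lower, Cd5 (77.1 to 20.7 FPKM) and Ahr, in the authors' deposited table (5 and 2 adjusted over the list alone; median 0.74, random -0.24 to 0.44). Plasma-cell markers had 3 of 7 higher and 0 lower (3 adjusted over the list alone; median 0.88), Igj, Mzb1 and Prdm1, which rose from 9.49 to 38.8 FPKM in the authors' deposited table. B-cell identity genes had 1 of 15 higher (1 adjusted over the list alone; median -0.19), Ms4a1, from 325 to 775 FPKM in the authors' deposited table. B-cell receptor and NF-kB targets had 1 of 18 higher, Myc, and 3 lower, with the NF-kB inhibitors Tnfaip3 (287 to 76.4 FPKM) and Nfkbia (181 to 59.5 FPKM) in the authors' deposited table (2 and 3 adjusted over the list alone; median -0.26). Uhrf1 was the 1 of 12 in DNA methylation machinery that rose, from 6.48 to 22.9 FPKM in the authors' deposited table (1 higher and 1 lower adjusted over the list alone; median -0.19).

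Cell cycle genes in Het_CLL had 1 of 19 higher, Mki67, with a log2 fold of 1.18 in the authors' deposited table (1 adjusted over the list alone; median 0.64, random -0.30 to 0.43). Lymphoma oncogenes had 3 of 17 higher, Evi5, Ccnd2 and Pvt1, the last from 6.07 to 26.4 FPKM in the authors' deposited table (3 adjusted over the list alone; median -0.11). Myeloid markers had 2 of 12 higher, S100a8 and S100a9, and 1 lower, Cebpb (4 and 1 adjusted over the list alone, median 2.19). Which of the sorted cells expressed these genes, or Itgam, was not tested. Erythroid markers had 3 of 7 lower by name (4 adjusted over the list alone; median -2.23), Beta-s and the haemoglobin genes Hba-a1 and Hba-a2, which share 1 entry at 137 to 18.8 FPKM in the authors' deposited table, as Hbb-b1 and Hbb-b2 share another. Cytotoxic effector genes had 2 of 14 lower, Eomes and Prf1 (3 adjusted over the list alone; median -1.67). Inhibitory receptors and exhaustion genes had 1 of 11 higher, Entpd1 (1 adjusted over the list alone; median -1.02). For p53 targets it was 1 of 13 higher, Pmaip1 (1 adjusted over the list alone; median -0.45), and imprinted genes 1 of 10 lower, Igf2r (1 adjusted over the list alone; median 0.05). No interferon-stimulated gene of 13 (median -0.07) and no germline gene of 2 (median 0.83) passed, also adjusted over the list alone, and 0 developmental regulators were measured. The Het_CLL table lists assembled loci, so its folds cannot be set beside those of the Mut_CLL table by size. In all, 881 of the 17344 entries tested were higher and 427 lower, 535 and 275 of them with a gene name. Of the lower genes 245 had a WT_CD8 value, and in 77 of them (31.4%, against 44.9% of all genes) WT_CD8 did not lie above WT_B1a, a restriction chosen after seeing the data that compares FPKM of separate tables.

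Mut_CLL showed proliferation genes and markers of other blood lineages rising together. Which of the sorted cells expressed these genes was not tested. Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, rose from 5.72 to 27.5 FPKM (log2 fold 2.27) and Plk1, a mitotic kinase, from 2.23 to 10.3 FPKM (2.21) in the authors' deposited table. S100a9 rose from 7.47 to 1673 FPKM (7.81), Lyz2, a lysozyme of myeloid cells, from 11.6 to 317 FPKM (4.77), and Hba-a1 from 98.8 to 687 FPKM (2.80) in the authors' deposited table. Igf2, an imprinted growth factor gene, rose from 0.105 to 85.5 FPKM (9.66, Cuffdiff q = 0.0395) in the authors' deposited table. Gnb3, a G-protein subunit gene, rose from 0.236 to 90.3 FPKM (8.58, Cuffdiff q = 0.0325) in the authors' deposited table. The falls included the complement receptor gene Cr2, from 102 to 11.8 FPKM (-3.11) in the authors' deposited table.

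Of 20 cell cycle genes 14 rose and 0 fell in Mut_CLL (15 adjusted over the list alone; median log2 fold 1.58, random lists -0.27 to 0.33). Beside them, 10 of 15 myeloid markers rose and 0 fell (12 adjusted over the list alone; median 4.77). Of 11 erythroid markers 8 rose and 0 fell, Hba-a1 and Hba-a2 from 1 shared entry (10 adjusted over the list alone; median 3.35), with Slc4a1 from 0.143 to 15.9 FPKM and Rhag listed at 0 in WT_B1a in the authors' deposited table. T-cell identity genes had 14 of 19 lower and 0 higher (15 lower and 1 higher adjusted over the list alone; median -1.41, random -0.24 to 0.37), with Cd28 at 62.8 to 13.6 FPKM in the authors' deposited table. B-1a cell markers had 5 of 14 higher and 4 lower (6 and 4 adjusted over the list alone, median 0.67). Among the higher were Itgam (1.64 to 54.0 FPKM), Zbtb32 (10.3 to 225 FPKM) and Bhlhe41 (22.6 to 79.5 FPKM) in the authors' deposited table. Among the lower was Cd5 (85.4 to 32.6 FPKM) in the authors' deposited table. Whether Itgam rose in B cells or together with the myeloid markers was not tested. B-cell identity genes had 1 of 16 higher, Ms4a1, and 1 lower, Cr2 (1 and 1 adjusted over the list alone; median 0.13). CLL-associated genes had 0 of 9 higher and 4 lower, with Fcer2a and Lef1 (1 and 4 adjusted over the list alone; median -0.05). B-cell receptor and NF-kB targets had 4 of 18 higher, with Egr1 at 55.3 to 212 FPKM in the authors' deposited table, and 4 lower, with Tnfaip3 (5 and 4 adjusted over the list alone; median 0.05).

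Interferon-stimulated genes had 5 of 16 higher and 0 lower in Mut_CLL, among them Rsad2, Oas2 and Oas3 (6 adjusted over the list alone; median 0.76, random -0.31 to 0.68). Cytotoxic effector genes had 5 of 16 higher and 0 lower, with Gzmb at 1.60 to 15.6 FPKM and Ccl5 at 66.7 to 409 FPKM in the authors' deposited table (5 adjusted over the list alone; median 0.82). DNA methylation machinery had 2 of 12 higher, Cdca7 and Uhrf1, the latter from 7.21 to 37.1 FPKM in the authors' deposited table (2 adjusted over the list alone; median 0.05). Lymphoma oncogenes had 3 of 17 higher, Pvt1, Evi5 and Ccnd2, and 1 lower, Stat5b (3 and 1 adjusted over the list alone; median 0.01). Inhibitory receptors and exhaustion genes had 1 of 11 higher, Entpd1, and 3 lower, Nr4a3, Tox and Nr4a2 (1 and 3 adjusted over the list alone; median -0.07). Imprinted genes had 1 of 10 higher, Igf2, and 2 lower, Impact and Igf2r (1 and 2 adjusted over the list alone; median -0.45). Plasma-cell markers had 1 of 7 higher, Igj (1 adjusted over the list alone; median 0.57). Among p53 targets 2 of 13 were lower, Tnfrsf10b and Trp53inp1 (2 adjusted over the list alone; median -0.02), and germline genes 0 of 1 (0 adjusted over the list alone; median -0.27), with 0 developmental regulators measured. In all, 758 of 11593 entries were higher and 392 lower, and an entry can hold more than 1 gene name. Counted by name, 393 lower genes had a WT_CD8 value. Of these, 157 (39.9%, against 51.9% of all genes) remained where WT_CD8 did not lie above WT_B1a.

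Genes higher in both CLL groups by the authors' tests numbered 289, Zbtb32, Itgam, S100a9 and Igj among them, where independent lists would share 29.6. A simulation of unchanged genes with shared controls gave 0, which its adjusted threshold fixed in advance. Genes lower in both numbered 137 (independent 8.27), with Tnfaip3, Cd5 and Lef1. At an unadjusted p under 0.05, 784 genes were higher in both, against 102 in the simulation. These counts take each gene name once, and some names share an entry of the Het_CLL table. The simulated genes change in no group, so the excess cannot separate changes shared by the tumours from the make-up of WT_B1a. Over 10264 genes the folds of both groups correlated at 0.439, where shared controls alone would give 0.730. Their covariance was 0.921, against 0.456 for shared controls alone. Part of the excess may come from the shared WT_B1a libraries, and 37 of the genes lower in both were left where WT_CD8 did not lie above WT_B1a.

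Mut_PTCL raised proliferation, interferon-response and killer-cell genes. Aurkb, a mitotic kinase, rose from 1.11 to 18.1 FPKM (log2 fold 4.03) and Mki67, a marker of cycling cells, from 3.23 to 48.4 FPKM (3.90) in the authors' deposited table. Usp18, a brake on interferon signalling, rose from 2.21 to 67.7 FPKM (4.94), and Gzmb from 10.1 to 194 FPKM (4.26) in the authors' deposited table. Ly6a, a surface protein of activated lymphocytes, rose from 12.05 to 532 FPKM (5.46) in the authors' deposited table, and its gene end went from 61.4% to 4.92% methylation. Thy1, a T-cell surface protein, fell from 105 to 4.39 FPKM (-4.58), Ctla4 from 123 to 4.31 FPKM (-4.84) and Ramp3, a receptor partner, from 122 to 0.701 FPKM (-7.44) in the authors' deposited table.

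All 17 measured interferon-stimulated genes rose in Mut_PTCL (17 adjusted over the list alone; median log2 fold 3.11, random lists -0.40 to 0.42), and 16 of 20 cell cycle genes rose and 0 fell (17 adjusted over the list alone; median 3.08, random -0.37 to 0.38). Cytotoxic effector genes had 9 of 16 higher and 0 lower (11 and 1 adjusted over the list alone; median 1.18), with the transcription factor genes Eomes at 21.4 to 126 FPKM and Tbx21 at 13.7 to 42.7 FPKM in the authors' deposited table. B-cell receptor and NF-kB targets had 1 of 18 higher and 10 lower (1 and 11 adjusted over the list alone; median -1.75), with Tnfaip3 at 846 to 124 FPKM and Relb at 64.0 to 13.3 FPKM in the authors' deposited table. DNA methylation machinery had 6 of 13 higher, with Cdca7 (3.67 to 34.0 FPKM), Uhrf1 (5.21 to 43.7 FPKM), Dnmt1 (28.2 to 84.0 FPKM) and Dnmt3b (2.68 to 7.45 FPKM), and 1 lower, Tet1, in the authors' deposited table (6 and 1 adjusted over the list alone; median 0.21). T-cell identity genes had 1 of 19 higher and 6 lower, with Ccr7 at 989.9 to 178 FPKM and Il7r at 186 to 38.1 FPKM in the authors' deposited table (1 and 6 adjusted over the list alone; median 0.10). Lymphoma oncogenes had 4 of 15 higher, with Pim2 at 54.4 to 228 FPKM in the authors' deposited table, and 3 lower, with Bcl6 (4 and 3 adjusted over the list alone; median 0.09).

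Erythroid markers had 5 of 6 lower in Mut_PTCL, Hba-a1 and Hba-a2 from 1 shared entry (6 adjusted over the list alone; median -2.18), and myeloid markers 1 of 5 higher, Cd68, and 1 lower, S100a9 (2 and 2 adjusted over the list alone; median -0.26). CLL-associated genes had 3 of 8 higher, with Bcl2 at 49.9 to 194 FPKM in the authors' deposited table, and 1 lower, Lef1 (3 and 3 adjusted over the list alone; median 0.39). B-1a cell markers had 3 of 9 lower, Ctla4, Ahr and Cd9 (4 adjusted over the list alone; median -0.74). B-cell identity genes had 2 of 11 higher, Cd22 and Cd79b (2 adjusted over the list alone; median 0.12), and plasma-cell markers 1 of 5 higher, Igj, and 1 lower, Irf4 (1 and 1 adjusted over the list alone; median 0.82). Imprinted genes had 1 of 9 higher, Igf2r, and 3 lower, Peg13, Impact and Cdkn1c, the last listed at 0 in Mut_PTCL (1 and 4 adjusted over the list alone; median -0.11). The p53 targets had 4 of 15 higher, with Phlda3, and 3 lower, with Tnfrsf10b (4 and 3 adjusted over the list alone; median -0.16). Inhibitory receptors and exhaustion genes had 1 of 10 higher, Entpd1, and 2 lower, Nr4a3 and Nr4a2 (2 and 3 adjusted over the list alone; median -0.26). The single measured germline gene (median 0.03) and developmental regulator (median -3.53) did not pass, also adjusted over the list alone. In all, 997 of 10918 genes were higher and 828 lower.

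**Figure D4:**
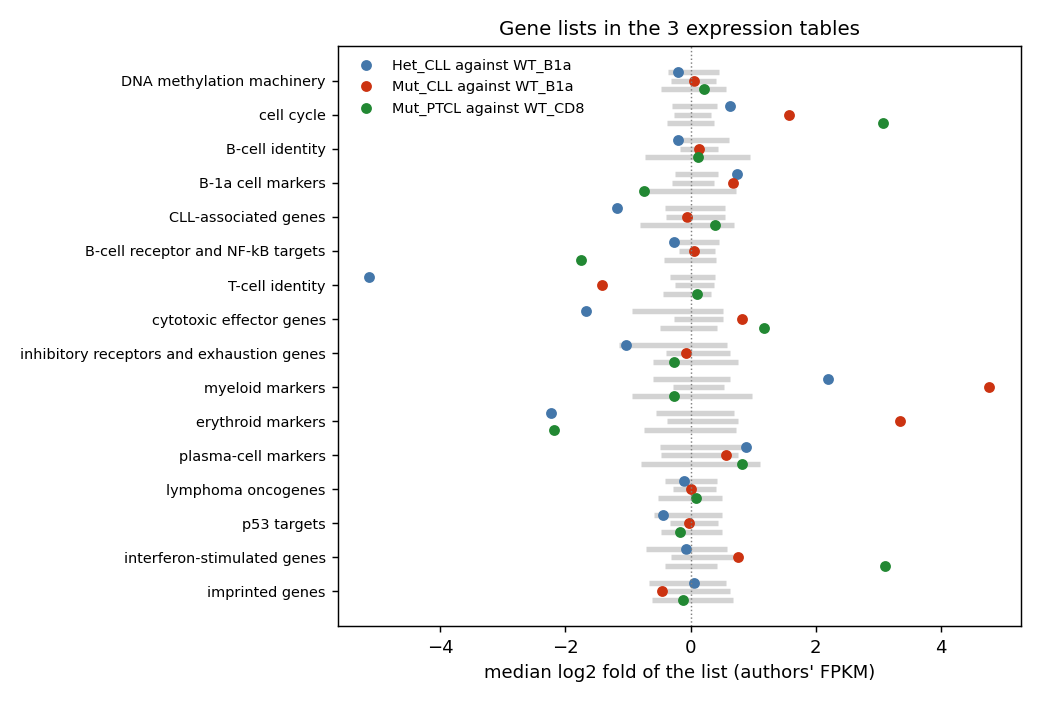
Median log2 fold of each gene list in the 3 expression tables, from the authors' deposited FPKM, with the range of matched random lists in grey. Medians are to be read against the random range of their own table, since fold sizes cannot be set beside each other between tables: the T-cell identity median lay below that range in Het_CLL and in Mut_CLL and inside it in Mut_PTCL.

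Genes that lost methylation tended to be expressed at higher levels in each tumour. In Mut_PTCL, the chemokine receptor gene Ccr2 (72.9% to 12.1%) rose from 6.83 to 168 FPKM in the authors' deposited table. In Mut_CLL, Crip1 rose from 389.7 to 2039.7 FPKM, and Capn2, a calcium-dependent protease gene (gene end 78.9% to 1.80%), from 19.9 to 53.6 FPKM in the authors' deposited table. In Het_CLL, Ly6d rose from 662 to 1992 FPKM and the chemokine receptor gene Ccr1 (87.1% to 30.6%) from 5.18 to 31.7 FPKM in the authors' deposited table. Among Het_CLL genes with a lower locus, 83 were measured, with a median log2 fold of 0.50 (random lists matched on expression: -0.02 to 0.29), and 20 passed as higher and 0 as lower, where 3.78 and 1.74 would be drawn at random. For Mut_CLL the median over 672 genes was 0.40 (random 0.02 to 0.12; 130 higher and 14 lower, 44.6 and 23.2 at random), and for Mut_PTCL it was 0.89 over 134 genes (random -0.16 to 0.16; 47 higher and 4 lower, 12.5 and 10.3 at random). With a limit of 20 points the medians were 0.34, 0.23 and 0.49. Genes with a more methylated gene end had a median log2 fold of -0.74 in Het_CLL (33 genes, random -0.70 to 0.25). There 0 passed as higher and 6 as lower, Lat, Lck and Bcl11b among them (1.48 and 0.68 at random). In Mut_CLL the median was -0.58 (15 genes, random -0.33 to 0.91), with 1 higher and 2 lower, Bcl11b and Cpne8 (1.01 and 0.53 at random). In Mut_PTCL it was -0.82 (12 genes, random -0.61 to 0.80). The calls there, 1 higher and 1 lower, Ell2, lay near the 1.11 and 0.94 at random. Methylation came from 1 library per group and genes are not independent replicates, so these values rank genes within the samples at hand. T cells among the sorted WT_B1a cells, taken up below, could give the same pairing in both CLL comparisons. No restriction by WT_CD8 was applied to these genes, so this was not tested. The Mut_PTCL comparison does not use WT_B1a.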

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

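The tests of chromosomes 15 and 17 alone and of chromosome 14 alone were chosen after the result was seen; the other tests of coverage were fixed before it.

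The tumour effect on RRBS methylation differed between Mut_CLL and Mut_PTCL at 219 tiles, and at 0 with the replicate number as a block. By edgeR the count was 0 without either library of WT_B1a or of WT_CD8 or without Mut_PTCL replicate 2, and 449 without Mut_PTCL replicate 1, so the number of tiles is uncertain (unadjusted p under 0.05 with all libraries: 4642; limma 172). The unadjusted count also asks for a difference of at least 10 points. At any difference, 6570 of 69973 tiles had an unadjusted edgeR p under 0.05. The labels compare different tumours with different normal cells, and the data cannot separate tumour type from cell of origin.

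Whole chromosomes stood out in the coverage of the CLL libraries. WGBS coverage relative to WT_B1a was 1.49 on chromosome 15 and 1.46 on chromosome 17 in Het_CLL, and 1.44 on chromosome 15 and 1.38 on chromosome 14 in Mut_CLL. In RRBS, chromosome 15 stood at 1.40 and 1.43 in Mut_CLL replicates 1 and 2 relative to the normal libraries. Chromosome 14 stood at 0.966 and 0.985 in the same libraries, so its rise in WGBS was not seen there. The oncogene Myc and its neighbour Pvt1 lie on chromosome 15.

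A few regions of very high coverage were tested as a source, but the WGBS ratios are medians over 1 Mb bins without sites of more than 200 calls. A few regions cannot raise such a median, so the outcome was fixed in advance. The bins do show how far the rise extends. On chromosomes 15 and 17 the 10th percentile over 1 Mb bins was at least 1.33 times WT_B1a. Over all 4 chromosome and library pairs the lowest 10th percentile was 0.562, because chromosome 14 of Mut_CLL held a lower middle segment. On that chromosome 100 of 122 bins (82.0%) lay above 1.1 times WT_B1a. Its ratio of 1.38 is the median of the same bins and already places most of them above that limit. A copy gain that other CLL tumours of the series also carry may be the source on chromosome 15: its genes lay above the other autosomes by at least 0.503 in median log2 fold in both CLL expression tables. A karyotype or DNA copy-number assay of the same tumours would separate gain from a technical effect on coverage, and was not analysed here.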

How the results depend on the processing

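The tests of gene-end windows in every setting, with WT_CD8, of limma with single libraries left out, of sites of over 200 calls and of the log2 folds of loci higher in Het_CLL were chosen after the result was seen. Except where a change follows from the setting itself, the cause was not tested.

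Allowing a difference of 20 points in WGBS raised every count by construction. In Het_CLL, 92411 tiles were lower and 14554 higher, 410 gene loci lower and 73 higher, and 1205 gene-end windows lower and 415 higher. In Mut_CLL the tiles were 462747 and 5596, the loci 3845 and 38, and the gene-end windows 4134 and 348. In Mut_PTCL the tiles were 131334 and 14072, the loci 601 and 41, and the gene-end windows 1061 and 358. Both CLL libraries were lower at 329 loci and 799 gene-end windows. The median log2 fold of genes with a lower locus was 0.34 in Het_CLL, 0.23 in Mut_CLL and 0.49 in Mut_PTCL, and that of genes with a lower gene end 0.20 in Het_CLL and 0.33 in Mut_PTCL. With 1 FPKM added before the log, the Mut_PTCL locus median was 0.77.

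Asking for 10 calls per CpG left 15 loci higher in Het_CLL, 8 in Mut_CLL and 7 in Mut_PTCL, and 118685 tiles lower and 1172 higher in Mut_CLL. The pooled mean levels of WT_B1a, Het_CLL, Mut_CLL, WT_CD8 and Mut_PTCL moved little: 80.9%, 78.5%, 78.5%, 79.5% and 80.1% at 10 calls, 80.3%, 77.9%, 77.7%, 78.9% and 79.4% at 1 call, and 81.1%, 78.6%, 78.2%, 79.6% and 80.3% over sites measured in all 5 libraries. The mean over sites was 79.3%, 76.0%, 65.4%, 77.0% and 72.4%, and the pooled mean without sites of over 200 calls was 81.2%, 76.9%, 66.0%, 79.4% and 74.7%. These last 2 settings give the few positions of very high coverage less weight.

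Centring the differences on their median left 36 loci higher in Het_CLL. In Mut_CLL it left 56182 tiles lower and 8496 higher, 164 loci lower and 61 higher, and 577 gene-end windows lower and 328 higher. In Mut_PTCL 5349 tiles were higher and 103 loci lower. Windows of 500 bp on each side of the gene end gave 277, 219 and 193 higher in Het_CLL, Mut_CLL and Mut_PTCL, and taking either gene end gave 732, 3624 and 801 lower. The ±500 bp setting was not run for gene loci, which have no such window, and planned RRBS promoter results were not run because no mm9 annotation was used here.

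Leaving out regions where WT_CD8 could have moved WT_B1a towards the call left 47 loci lower and 11 higher in Het_CLL, 628 lower in Mut_CLL and 27 lower in both. For gene-end windows it left 218 lower and 70 higher in Het_CLL, 59 higher in Mut_CLL and 131 lower in both, and for tiles 13378 lower and 1759 higher in Het_CLL and 124887 lower and 955 higher in Mut_CLL. Of genes with lower expression and a WT_CD8 value, 77 of 245 were left in Het_CLL, 157 of 393 in Mut_CLL, and 37 in both. This setting removes regions and genes by construction, whatever the make-up of WT_B1a. No other WT_B1a library exists for WGBS, and the comparison of Mut_CLL with Het_CLL is free of it.

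In RRBS, a limit of 25 points left 645 tiles higher in Mut_CLL and 257 in Mut_PTCL, and 20 calls per CpG left 55 tiles with a different tumour effect. Replicate numbers shared by the groups do not pair the samples: the correlations of deviations of same-numbered libraries lay between -0.135 and 0.0637. With the replicate number as a block, edgeR called 469 tiles lower and 267 higher in Mut_PTCL, 0 for the interaction (unadjusted p under 0.05: 4402; limma without the block 172) and 0 between the normal cell types (1623; limma without the block 109). The counts of lower and higher tiles in Mut_CLL with the block stayed within a factor of 1.5 of those without it.

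Leaving out single RRBS libraries gave 0 to 5634 tiles lower and 0 to 2327 higher in Mut_CLL by edgeR, and 0 to 4790 and 0 to 2107 by limma. In Mut_PTCL the ranges were 0 to 1462 lower and 0 to 870 higher by edgeR, and 0 to 1319 and 0 to 892 by limma. The interaction ran from 0 to 771 by edgeR and from 0 to 497 by limma, and the difference of the normal cell types was 0 in each case by both tools. The zeros came without WT_B1a replicate 1 (unadjusted p under 0.05 by edgeR and limma: Mut_CLL lower 4518 and 4291, interaction 2717 and 2683) or 2 (4724 and 4474, 2857 and 2813), and without WT_CD8 replicate 1 (Mut_PTCL lower 2470 and 2403, interaction 3189 and 3155) or 2 (2530 and 2444, 3142 and 3099), and for the interaction also without Mut_PTCL replicate 2 (5816 and 5545) and, by limma, replicate 1 (6545). Without Mut_CLL replicate 1, 3128 tiles were lower and 720 higher by edgeR, with 650 higher by limma, and the interaction held 540 and 343 tiles; without Mut_CLL replicate 2 it held 771 and 497. Without Mut_PTCL replicate 1, 1137 tiles were lower and 347 higher, and the interaction held 449 tiles by edgeR. In these fits the lone sample of an arm is assumed to vary like the other groups.

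The RRBS mean difference of Mut_CLL ran from -3.55 to -0.861 points with single libraries left out, and was -0.363 as a mean over sites. That of Mut_PTCL ran from -0.669 to 2.09, turning negative without Mut_PTCL replicate 1 (-0.669) and without WT_CD8 replicate 2 (-0.454), and was 0.0197 as a mean over sites.

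A q under 0.01 left 556 genes higher in Het_CLL, 428 higher and 260 lower in Mut_CLL, and 160 higher and 86 lower in both, fewer by construction.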

Other observations

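The tests of T-cell RNA in WT_B1a, of Trdd1 to Trdc against Het_CLL alone, of the opposite tiles, of T-cell shares, of Cd3d and of bisulfite conversion were chosen after the result was seen; only those of the 35 tiles, of Trdd1 to Trdc against both CLL libraries and of low coverage were fixed before it.

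Some of the 5 receptor loci examined had less coverage in the cells that rearrange them. From Ighj1 to Ighd1-1, the joining end of the antibody heavy chain locus, WGBS coverage relative to the flanks was 0.662 in WT_B1a, 0.0347 in Het_CLL and 0.272 in Mut_CLL, against 0.998 in WT_CD8 and 1.01 in Mut_PTCL. From Trdd1 to Trdc, the T-cell receptor delta segments that alpha chain rearrangement deletes, it was 0.465 in WT_CD8 and 0.0584 in Mut_PTCL, and 0.879, 1.22 and 1.56 in WT_B1a, Het_CLL and Mut_CLL. From Trbd1 to Trbc1 it was 0.326 in WT_CD8 and 0.348 in Mut_PTCL, but also only 0.663, 0.810 and 0.732 in WT_B1a, Het_CLL and Mut_CLL. From Igkj1 to Igkc it was 0.731 in Het_CLL and 0.873 in Mut_CLL, but 1.49 in WT_B1a, as in WT_CD8 (1.39) and Mut_PTCL (1.43), and from Traj61 to Traj1 it was 1.04 in WT_CD8 and 0.890 in Mut_PTCL, against 1.19, 1.31 and 1.91, where, as at Trdd1, the flanks in Mut_CLL cross a change of coverage.

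Parts of chromosomes also differed in coverage. Het_CLL held 0.499 of the WT_B1a level over chromosome 13 from 13 to 56 Mb, where 211 genes had a median log2 fold lower by -0.40 than the rest. Mut_CLL held 0.556 over chromosome 14 from 55 to 76 Mb (137 genes, -0.09), with 1.36 and 1.53 on either side (-0.06 and -0.07), and 0.660 over chromosome 2 from 81 to 92 Mb (43 genes, -0.28). On chromosome 14 neither the RNA nor the RRBS coverage of Mut_CLL (0.966 and 0.985 over the whole chromosome) showed a matching change. The RNA values pool 8 libraries and RRBS has 2, and the labels do not say whether any comes from the tumour of the WGBS library. These values therefore cannot show whether RNA followed coverage in that tumour. Coverage of X over the autosomes was 1.05, 1.11, 0.720, 1.13 and 1.34 in WT_B1a, Het_CLL, Mut_CLL, WT_CD8 and Mut_PTCL.

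T cells among the sorted WT_B1a cells may account for part of the lower methylation of T-cell genes, and higher methylation of B-cell genes, in WT_B1a than in both CLL libraries. In 35 tiles at 80% or more in both CLL libraries and 20% or less in WT_CD8, the median WT_B1a level was 56.8%, with 71.4% of tiles within 20 points of it, which a share of 41.3% T cells would give; 1690 tiles of the opposite kind (20% or less in both CLL libraries, 80% or more in WT_CD8) stood at 68.6%, and 104 such RRBS tiles at 68.9% and 69.3%, which would take 76.7%, 77.6% and 77.5%, so 1 share does not account for both kinds. Coverage from Trdd1 to Trdc in WT_B1a was 0.632 of the mean of both CLL libraries and 0.719 of Het_CLL alone, and the T-cell identity list had a median log2 fold of -1.41 in Mut_CLL, with 0 of its 19 genes in another list. Cd3d is listed at 67.5 FPKM in WT_B1a and 389 FPKM in WT_CD8 in the authors' deposited tables, which were normalized apart. RNA of this T-cell gene was thus present in the WT_B1a libraries. Its lower level there goes only against shares as large as the tiles give, and those come from other libraries. From Ighj1 to Ighd1-1, WT_B1a coverage was 0.662 of its flanks, between the CLL libraries (0.0347 and 0.272) and WT_CD8 (0.998). From Igkj1 to Igkc it was 1.49, as in WT_CD8 (1.39). At the T-cell receptor loci too, WT_B1a lay between WT_CD8 and both CLL libraries. Each value comes from 1 library, without another normal B-cell library as a reference. Normal B-1a cells that differ from the tumours' cell of origin remain an untested explanation, and a sort that excludes CD3-positive cells would remove T cells.

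CpG-dense tiles with little methylation in WT_B1a were in part higher in Mut_CLL: 21 of 165 (12.7%) by at least 30 points. The same was seen at 38 of 448 (8.48%) in Het_CLL, which keeps a Dnmt3a allele, and at 24 of 873 (2.75%) in Mut_PTCL against WT_CD8. Incomplete bisulfite conversion throughout the library could raise such tiles, but the median difference over all 165, called or not, was 0.179 points; a failure confined to some tiles was not tested. Low coverage could do so by chance, but 87.5% of those measurable at 10 calls, 14 of 16, stayed higher by 30 points. Another methyltransferase, such as Dnmt3b, and selection of methylated cells during tumour growth remain untested explanations.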
